A study of Danio rerio with 9 samples.

How the data were processed

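The series holds 9 libraries of polyadenylated RNA from whole zebrafish embryos, 3 each from embryos injected with a control, a dhps or an eif5a1/2 morpholino. Per the labels' protocols, RNA was extracted with trizol and chloroform, enriched on oligo(dT) beads, fragmented, copied with random primers and amplified by PCR, and the libraries were made as circular single-stranded DNA. The protocol notes place the extraction 24 hours after the morpholino, and the series design places it 24 hours after fertilization. The reads were processed by the submitters against the GRCz11 assembly, per the submitters' processing notes. The aligner, the counting tool, the annotation version, the use of strand and the authors' own test are not given in the sources used here.

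The main table holds 24614 genes, each marked as mRNA, with a value per gene and library in 2 units. The authors deposited expected counts, which are estimates that can split reads between similar transcripts, per the file headers. Between 91.4% and 93.95% of these counts were whole numbers per library, within a tolerance of 1e-06. The same deposited table gives TPM per the file headers. Further deposited tables hold the authors' own comparisons, with a log2 fold change, a p-value and a q-value per gene, and in the dhps comparison also the −log10 of the q-value, per the file headers.

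The expected counts were rounded to whole numbers, because the planned test needs counts and the files hold estimates. Genes with low counts were left out with edgeR's filterByExpr, which left 17031 genes that held at least 99.84% of the reads of each library. Library sizes were scaled with edgeR's trimmed mean of M-values (TMM). Each comparison used edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in 1 fit to all 9 libraries, with 3 groups, no covariate and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called changed. Unless another tool is named, each adjusted p of a gene is from this test. CPM values are counts divided by these scaled library sizes and brought to a common total. Fold changes are given as log2, with the SE derived from the quasi-likelihood F statistic. The common biological coefficient of variation was 0.225.

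For lists of genes, camera (limma 3.58.1) was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and its p-values were adjusted by Benjamini-Hochberg over the 38 lists tested in a comparison. It asks whether members of a list lie higher or lower than other genes, so a list can be called with few members past the test of single genes. The calls were set beside camera with an estimated correlation, given at each list, and beside fry, given mainly for the lists it did not call. A call lost with an estimated correlation need not come from correlation between members. For endocrine pancreas in eif5a1/2 against control the estimate was -0.0141, below the preset 0.01. Its camera adjusted p still went from 0.000474 to 0.0892. Fry asks whether the genes of a list move one way without comparing them with other genes. All 39 lists were written from general knowledge of the genes, and the list of genes of the mitochondrial genome matched 0 genes in the table. A gene and a list are not reported here, and counts of lists include that list. Symbols were matched in the table itself or through the gene IDs of an NCBI table of the assembly GRCz12tu, which was used for names and for the order of neighbouring genes. Of the 24614 gene IDs, 22941 were found there, and 82 symbols of the lists were matched by another name of the same gene ID. No genome sequence or annotation of GRCz11 was used here, and no coordinates are given.

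The genes named were set by rule. Named whatever their p were the targets dhps, eif5a and eif5a2 with dohh. In each comparison the rule took the 6 highest and 6 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean CPM of at least 1, groups whose CPM did not overlap and a given name. It also took up to 4 members with the smallest adjusted p of each list described. The groups, the test, the lists, this rule and the following other settings were fixed before the data were examined. They were another scaling (RLE), library totals alone, no filter, a stricter filter, the replicate number as a block, each library left out in turn, the 2 compared groups fitted alone, DESeq2 (1.42.0), limma-voom, a 2-fold minimum, an adjusted p under 0.01, and, for the lists, an estimated correlation, fry and members that belong to 1 list only. After the data were seen, 6 more were added: the length slope of each library as a covariate, the length trend removed through offsets (loess with a span of 0.3), 1 surrogate variable (sva 3.50.0), the 5 libraries with a positive length slope alone, the 4 with a negative length slope alone and a paired fit of eif5a1/2 against control. The 5 libraries with a positive slope are the 3 of dhps with control 2 and eif5a1/2 2. Tests there assume that a lone library varies like the dhps libraries.

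The labels give equal replicate numbers to the groups and do not say what they share. Between control and eif5a1/2, the deviations of same-numbered libraries from their group means correlated at 0.403, 0.76 and 0.318 across genes, and 4 of 6 libraries correlated best with their own number. The differently numbered control 3 and eif5a1/2 1 correlated at 0.597, above the 0.403 and 0.318. By the rule that every pair lie over 0.1 the numbers were taken to pair these 2 groups. The paired fit holds these 6 libraries with the replicate number as a block. With dhps, 0 of 3 same-numbered pairs lay over 0.1 against control and 1 of 3 against eif5a1/2, so no pairing was taken there. The pairing comes from the values and not from the labels. In both groups number 2 is the library with a positive length slope, so a shared origin and that difference between libraries cannot be told apart. The block was chosen from the same values, so the counts and p-values of the paired fit are not independent support.

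The length slope is the slope of a library's log2 CPM, as a deviation from the mean of all libraries, on the log2 of relative transcript length. Relative length was taken from the ratio of counts to TPM at a TPM of at least 0.5, and 15550 of the tested genes (91.3%) had one. Without an annotation of the build, it is the length the authors' counting used, up to a factor.

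The steps were tested on simulated counts drawn from the means and library sizes of these libraries, in 5 runs with 100 genes changed 2-fold and 100 changed 4-fold. In the simulated dhps comparison with control, over 16790 genes, 48.8% of the 2-fold and 86.4% of the 4-fold changes were recovered and 4.3% of the calls were false. For eif5a1/2 against control (16787 genes) the shares were 47.8%, 89.6% and 4.1%, and for eif5a1/2 against dhps (16792 genes) 46.6%, 90.2% and 6.6%. In each of the 3 simulated comparisons, 5 of 5 shifted lists were called and 0 of 100 unshifted lists. The simulated genes were drawn independently and the simulated lists were random. In the data the estimated correlation between members of a list reached 0.971, for cytoplasmic ribosomal proteins. The simulated shares therefore check the steps and do not give the rate of false calls of genes or lists in these libraries. No 2 libraries held counts that agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of 1 group was 6.92, for dhps 2 and dhps 3. The depth was 15952644 to 17482536 counted reads per library. For a gene with 0 reads in a group, a floor of 3 counts per library was used for a lower bound of the fold. Floors cover counting error only, since PCR copies were not told apart. Nothing in the labels says that the libraries of a group came from separate clutches of embryos, so the p-values measure the spread between these samples, which may be technical. No second morpholino and no rescue were analysed here, so off-target effects of a morpholino were not tested.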

Results

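RNA was measured in whole zebrafish embryos 24 hours after fertilization, in 3 groups of 3 libraries. The embryos had been injected with a control morpholino, a dhps morpholino or an eif5a1/2 morpholino. Morpholinos are antisense oligomers that block the translation or the splicing of a transcript, and which of these was used is not given in the sources used here. The gene dhps encodes deoxyhypusine synthase, which starts the conversion of a lysine of the translation factor eIF5A to hypusine, and dohh encodes the hydroxylase that completes it. The series therefore sets targeting of the modifying enzyme beside targeting of the factor itself. The counts summed to 16834136, 17482536 and 17006113 reads in control 1, 2 and 3. They summed to 16779961, 16822047 and 16893447 reads in dhps 1, 2 and 3, and to 15952644, 17248752 and 16726714 in eif5a1/2 1, 2 and 3.

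The libraries differed along an axis that is not the injected morpholino alone. On the first principal component of log2 CPM, which held 62.6% of the variance, the dhps libraries scored 27.3 to 58.7, control 2 scored 24.4 and eif5a1/2 2 scored 59.18. Control 1, control 3, eif5a1/2 1 and eif5a1/2 3 scored -54.6, -72.6, -55.6 and -21.4. The 5 libraries on the positive side had length slopes of 0.039 to 0.141, against -0.126 to -0.067 in the other 4. The decile of genes with the shortest transcripts had median log2 deviations of -0.451 to -0.147 in these 5 libraries and 0.159 to 0.439 in the other 4. The longest decile was at 0.012 and -0.0067 in dhps 2 and 3. Across genes, the loading on the first component had a Spearman correlation of 0.404 with log2 relative length. Genes for cytoplasmic ribosomal proteins took 19.3% to 21.1% of the reads in the dhps libraries, 21.9% in control 2 and 17.95% in eif5a1/2 2. They took 29.0% and 31.2% in control 1 and 3 and 28.7% and 24.4% in eif5a1/2 1 and 3. The second component held 9.56%.

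**Figure D1:**
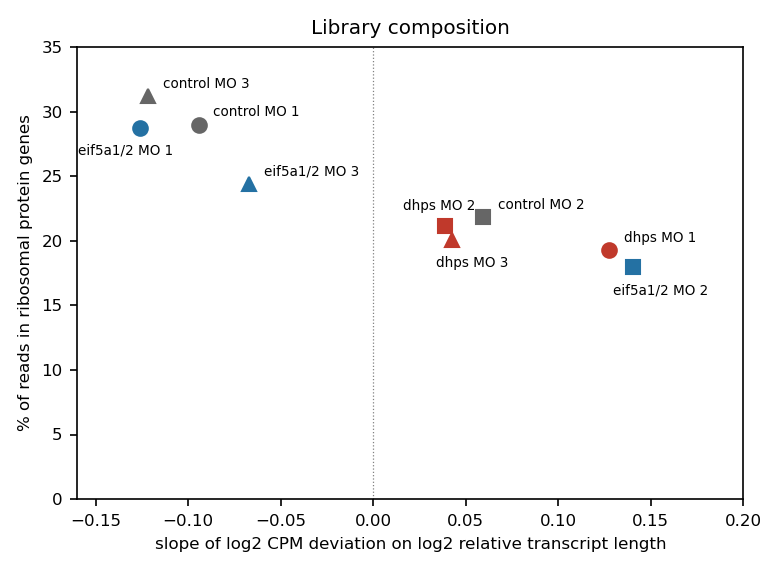
Each point is 1 of the 9 libraries, coloured by injected morpholino, with the share of reads in genes for cytoplasmic ribosomal proteins (percent) set against the library's length slope (log2 CPM per log2 relative length). The 3 dhps libraries, control 2 and eif5a1/2 2 lie at slopes of 0.039 to 0.141, and the other 4 libraries at -0.126 to -0.067.

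The transcripts named by the morpholinos were examined in every library first. The level of eif5a (gene ID 406464), whose synonym in the NCBI table is eIF-5A-1, was 1363 ± 169 CPM in control, 1085 ± 31 in dhps and 227 ± 13 in eif5a1/2 libraries (SD, n = 3 each). It fell by 2.58 ± 0.16 on the log2 scale (SE) in eif5a1/2 embryos against control (adjusted p = 0.000209). Against dhps embryos it fell by 2.26 ± 0.16 (adjusted p = 0.000151). The eif5a1/2 libraries held 213.3 to 238.4 CPM and no other library less than 1055. Its paralog eif5a2 (406546) had 278 ± 80, 400.2 ± 27 and 212.9 ± 68 CPM, and its difference in eif5a1/2 against control was within the spread (log2 -0.38 ± 0.26, adjusted p = 0.729). In dhps against control it was at 0.52 ± 0.26 (adjusted p = 0.286, deposited q-value 0.104). Against dhps it was at -0.91 ± 0.26 in eif5a1/2 embryos (adjusted p = 0.135, deposited q-value 0.0084). The CPM of the groups did not overlap in either of these comparisons. The 2 paralogs can share reads, so the split between them is uncertain.

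The dhps transcript (406329) was measured at 14.5 ± 1.4 CPM in control, 9.38 ± 1.0 in dhps and 14.9 ± 0.74 in eif5a1/2 libraries. In dhps embryos its log2 difference from control was -0.62 ± 0.13 with an adjusted p of 0.0508, short of the threshold. The authors' deposited table gives it -0.626 with a q-value of 0.0262. The 8.27 to 10.3 CPM of the dhps libraries lay below the 13.0 to 15.7 CPM of the controls. Adjusted over the list alone, the 4 genes of eIF5A and its hypusination, its p was 0.00269. Against dhps embryos it rose by 0.67 ± 0.13 in eif5a1/2 embryos (adjusted p = 0.0347), a call made in 2 of the 9 fits that leave out 1 library. A morpholino can act without lowering its transcript, so the levels check the labels of the eif5a1/2 group more firmly than those of the dhps group. The hydroxylase gene dohh (321732) had 78.4 ± 17, 74.3 ± 8.4 and 75.6 ± 23 CPM and no difference past the test (adjusted p = 0.858, 0.961 and 0.974), although with 1 surrogate variable it was called higher in dhps embryos (0.375, adjusted p = 0.0279). The list of these 4 genes, which holds the morpholino's own target, was called lower in eif5a1/2 than in control embryos (camera adjusted p = 0.0128; adjusted p = 0.175 with an estimated correlation). The member that fell was eif5a, 2 others had negative values and dhps a positive one, so the call says nothing of the list beyond the target.

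**Figure D2:**
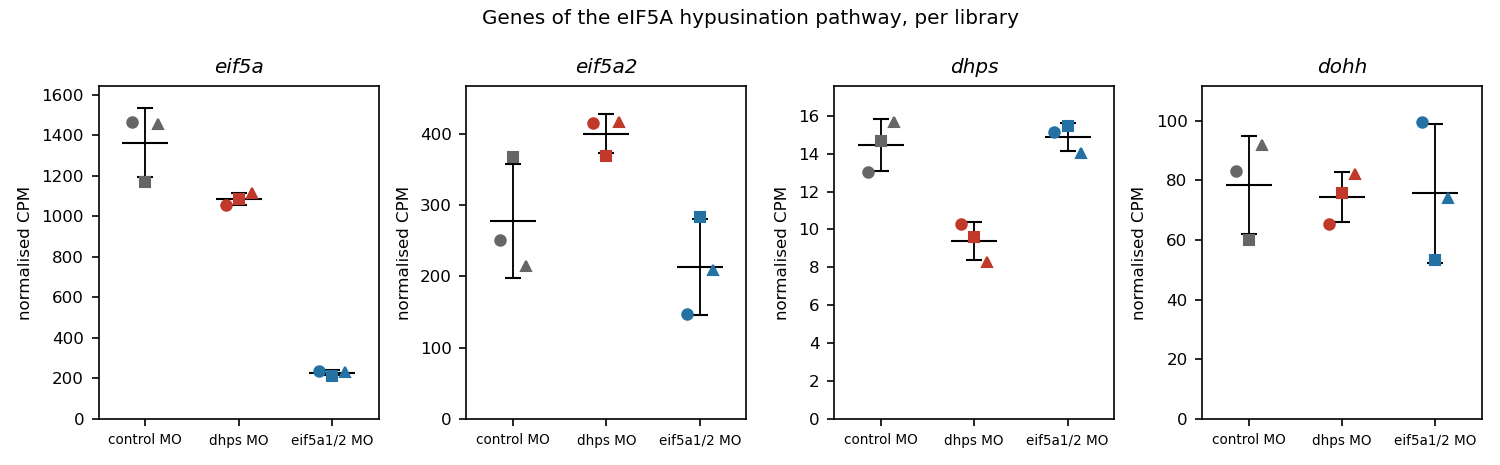
CPM of eif5a, eif5a2, dhps and dohh in each of the 9 libraries (points) with the group mean and SD (bars), by injected morpholino. The eif5a level is 213.3 to 238.4 CPM in the eif5a1/2 libraries and at least 1055 in the others, and the dhps level is 8.27 to 10.3 CPM in the dhps libraries and at least 13.0 in the others.

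The comparison of dhps with control morpholino asks which transcripts move when the enzyme that starts hypusination is targeted. In dhps embryos the ubiquitin ligase gene mdm2 rose by 1.51 ± 0.14 and the cell cycle inhibitor gene cdkn1a by 1.54 ± 0.16 (adjusted p = 0.00138 and 0.00228). The pro-apoptotic gene bbc3 (puma) rose by 1.4 ± 0.14 and sesn3, a sestrin of the stress response, by 1.15 ± 0.10 (adjusted p = 0.00182 and 0.00138). These 4 genes passed the test in 9 of 9 fits that leave out 1 library.

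Genes of neurons and of neural progenitors lay lower in dhps embryos relative to all genes, and their medians were positive under library totals alone, which moved all genes upward. Of 41 neuronal genes, 4 fell (8 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 4.62e-06; adjusted p = 0.0391 with an estimated correlation). Under library totals alone, where the median of all genes was 0.365, it was 0.12, or -0.25 relative to all genes (camera adjusted p = 0.000945). The genes that fell were those of the interneuron factor lhx5 (-1.05 ± 0.15), the proneural factor neurod4 (-0.63 ± 0.10), the neurofilament nefmb (-0.77 ± 0.14) and the interneuron progenitor factor dbx1a (-0.54 ± 0.10). Their adjusted p were 0.011, 0.02, 0.0359 and 0.0413, and they passed the test in 4, 4, 3 and 2 of the 9 fits that leave out 1 library. Of 47 genes of neural progenitors, 5 fell, and 13 fell and 1 rose adjusted over the list alone. Their median was -0.21, and 0.17 under library totals alone (camera adjusted p = 0.000126; adjusted p = 0.317 with an estimated correlation). The proneural gene ascl1b fell by 1.15 ± 0.11 and the radial glia marker fabp7a by 1.45 ± 0.17 (adjusted p = 0.00172 and 0.00408), each in 9 of 9 fits that leave out 1 library. Also lower were ascl1a (-0.85 ± 0.14, adjusted p = 0.02) and the Notch target her4.2 (-1.37 ± 0.20, adjusted p = 0.0113), the latter from a family of near-identical copies that can share reads. For retina and lens, 1 of 36 members fell, mab21l1 of eye development (-0.54 ± 0.10, adjusted p = 0.0334). The calls of ascl1a, her4.2 and mab21l1 held in 4, 5 and 3 of these fits. That list's median was -0.50, and -0.14 under library totals alone (camera adjusted p = 0.00146; adjusted p = 0.317 with an estimated correlation).

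Genes of yolk and lipoproteins were lower in dhps embryos, with a median of -0.50 over 26 members, -0.11 under library totals alone and -0.19 with the length slope as a covariate (camera adjusted p = 2.04e-05; adjusted p = 0.4 with an estimated correlation). A single member fell, the apolipoprotein gene apoa4b.3 (5 adjusted over the list alone). The triglyceride synthesis gene dgat2 was at -2.85 (adjusted p = 0.05) and the retinol carrier gene rbp4 at -1.11 (adjusted p = 0.0646). The list of liver and gut endoderm had a median of -0.15, which was 0.22 under library totals alone (camera adjusted p = 0.0236; adjusted p = 0.54 with an estimated correlation). Its call ended without control 1 (median -0.091, adjusted p = 0.0524). In it edgeR called 0 of 28 members, with 10 lower and 1 higher at an unadjusted p under 0.05, 7 lower by DESeq2 and 1 lower by limma-voom.

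Among the genes that rose most in dhps embryos was ace (565980), which encodes angiotensin converting enzyme, at 30.9 ± 1.9 CPM against 7.04 ± 1.0 in control (log2 2.14 ± 0.14, adjusted p = 0.000466). The gene crhr2 (100002312), for a receptor of corticotropin releasing hormone, was at 62.55 ± 21 against 8.11 ± 3.6 (2.93 ± 0.34, adjusted p = 0.00408). The large ubiquitin ligase gene rnf213b (563001) was at 3.75 ± 0.28 against 0.397 ± 0.060 (3.23 ± 0.31, adjusted p = 0.00172). The cell cycle inhibitor gene cdkn2a/b (100329528), the chemokine receptor gene cxcr3.1 (654692) and the sulfotransferase gene sult3st2 (322415) rose by 3.54 ± 0.66, 2.91 ± 0.47 and 2.48 ± 0.42. Their control levels were 0.249, 0.295 and 0.391 CPM, and their adjusted p 0.0377, 0.02 and 0.0261. Among those that fell most was mibp2 (386710), a muscle integrin binding protein gene, at 176.4 ± 11 CPM against 1061 ± 195 (log2 -2.59 ± 0.22, adjusted p = 0.00138). Lower as well were apoa4b.3 (100004607, -2.75 ± 0.30) and the coagulation protein gene prozb (558106, -2.55 ± 0.29), at adjusted p of 0.00307 and 0.00358. The selenoprotein gene fep15 (100329562, -2.78 ± 0.45), the chemotactic factor gene lect2l (567278, -2.66 ± 0.52) and the chitobiase gene ctbs (553763, -3.12 ± 0.55, from 8 reads over the 3 dhps libraries) had adjusted p of 0.02, 0.0463 and 0.0294.

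With 1 library left out at a time, ace, crhr2, rnf213b, mibp2, apoa4b.3 and prozb passed the test in 9 of 9 fits. The genes cdkn2a/b, sult3st2, fep15 and ctbs passed in 3, their calls ending without control 1, control 3, any dhps library or eif5a1/2 3. The calls of cxcr3.1 held in 5 fits and those of lect2l in 3.

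Genes for cytoplasmic ribosomal proteins lay lower in dhps embryos, 84 of 84 with a negative value and a median of -0.86, -0.44 under library totals alone (camera adjusted p = 5.28e-17; adjusted p = 0.54 with an estimated correlation). This list moved with the library axis as well as with the group. Relative to the control mean its median was -0.58 in control 2 and -0.91 to -0.69 in the dhps libraries, against 0.18 and 0.40 in control 1 and 3. Over the 5 libraries with a positive length slope, where control 2 is the lone control, the median of dhps against control was -0.19. The member that fell was rpl22l1, a paralog of rpl22 (-1.38 ± 0.24, adjusted p = 0.0294), in 3 of the 9 fits that leave out 1 library. Nuclear genes of oxidative phosphorylation had a median of -0.55, -0.14 under library totals alone (camera adjusted p = 2.42e-11; adjusted p = 0.54 with an estimated correlation) and moved with the same axis. Per library they ran from -0.57 to -0.43 in dhps and from -0.45 in control 2 to 0.30 in control 3. Their call ended with the length slope as a covariate (median -0.073, adjusted p = 0.0594, with a range of 9.18e-19 to 0.68 over the alternatives). In that list edgeR called 0 of 93 members, with 26 lower at an unadjusted p under 0.05, 4 lower by DESeq2 and 0 by limma-voom.

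Mitochondrial ribosomal proteins had a median of -0.37 in dhps embryos, which was 0.024 under library totals alone (camera adjusted p = 4.62e-06; adjusted p = 0.603 with an estimated correlation). It was 0.049 with the length slope as a covariate, and per library it ran from -0.50 to -0.30 in dhps and from -0.44 to 0.27 in control. For these genes edgeR called 0 of 76, with 8 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. Translation factors had a median of -0.28 that was 0.11 under library totals alone, where the call ended (adjusted p = 0.11; main camera adjusted p = 0.0439; adjusted p = 0.624 with an estimated correlation). The member that changed, the initiation factor gene eif3eb, rose (0.70, adjusted p = 0.0463, in 3 of the 9 fits that leave out 1 library). The call of this list ended without control 1 (adjusted p = 0.104), control 3 (0.0948) or dhps 1 (0.206). Per library its median ran from -0.37 to -0.16 in dhps and from -0.22 to 0.13 in control.

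Ribosome biogenesis genes were higher in dhps embryos, by a median of 0.15 over 81 members, 0.51 under library totals alone (camera adjusted p = 0.00101; adjusted p = 0.573 with an estimated correlation). The nucleolar phosphoprotein gene nolc1 rose by 1.23 ± 0.12 and the rRNA methyltransferase gene ftsj3 by 0.88 ± 0.17 (adjusted p = 0.00172 and 0.0385), and 6 members rose adjusted over the list alone. Of the 9 fits that leave out 1 library, nolc1 passed in 9 and ftsj3 in 3. The call ended without control 2 (median 0.088, adjusted p = 0.241). The median was 0.25 without dhps 1, 0.082 without dhps 3, 0.29 with the length slope as a covariate and 0.077 with the length trend removed. Mitosis genes lay at a median of -0.22, which was 0.15 under library totals alone (camera adjusted p = 0.00146; adjusted p = 0.193 with an estimated correlation). Of 39 members 30 were negative and 0 were called by edgeR, with 12 lower at an unadjusted p under 0.05, 2 lower by DESeq2 and 0 by limma-voom. Erythrocyte genes had a median of -0.38 that was 0.026 under library totals alone (camera adjusted p = 0.00125; adjusted p = 0.54 with an estimated correlation). The members that changed were mibp2, known from muscle, which fell, and klf3, a regulator of erythroid and other genes, which rose by 0.58 (adjusted p = 0.048). Glycolysis genes had a median of -0.25 that was 0.13 under library totals alone (camera adjusted p = 0.0209; adjusted p = 0.193 with an estimated correlation). The muscle enolase gene eno3 fell (-2.10 ± 0.30, adjusted p = 0.011) and the hexokinase gene hk2 rose (0.57 ± 0.10, adjusted p = 0.0294). The calls of klf3, eno3 and hk2 held in 1, 5 and 3 of these fits.

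Of 17031 genes tested in dhps against control, 220 changed (1.29%), of which 104 rose and 116 fell. Under library totals alone the split was 69 higher and 28 lower. At an unadjusted p under 0.05 there were 3324 genes, and the CPM of the groups did not overlap for 30.9% of genes, where chance gives 10%. The count was 807 without control 2 and 616 without eif5a1/2 2, but 59, 60 and 113 without control 1, control 3 and eif5a1/2 3 and 56, 81 and 44 without dhps 1, 2 and 3. DESeq2 gave 898, and the authors' deposited table lists 1178 genes at a q-value under 0.05, which include 219 of the 220.

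The comparison of eif5a1/2 with control morpholino asks which transcripts move when the factor itself is targeted. Genes of neurons were lower in eif5a1/2 embryos. Of 41 members, 39 had negative values, 1 fell and 40 did not pass the test, and 16 fell adjusted over the list alone. The list's median was -0.39, and -0.24 under library totals alone, where the median of all genes was 0.18 (camera adjusted p = 1.11e-15; adjusted p = 0.0022 with an estimated correlation). The member that fell was the beta tubulin gene tubb5 (-0.85 ± 0.13, adjusted p = 0.048), which passed the test in 0 of the 9 fits that leave out 1 library. The acetylcholine transporter gene slc18a3a was at -1.22 (adjusted p = 0.117, and 0.0211 in the paired fit), the growth cone gene stmn2a at -0.52 (adjusted p = 0.136) and the neuronal homeobox gene tlx2 at -0.64 (adjusted p = 0.155). Per library, the list's median was -0.42 to -0.38 in eif5a1/2, -0.28 to -0.21 in dhps and -0.014 to 0.015 in control libraries, so it did not follow the library axis.

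Genes of skeletal muscle had a median of -0.31 in eif5a1/2 embryos, -0.17 under library totals alone, with 46 of 57 negative (camera adjusted p = 7.81e-08; adjusted p = 0.191 with an estimated correlation). Here edgeR called 0 members (1 adjusted over the list alone), with 19 lower and 1 higher at an unadjusted p under 0.05, 2 lower and 1 higher by DESeq2 and 0 by limma-voom. The parvalbumin gene pvalb3 was at -1.30 (adjusted p = 0.135, and 0.002 in the paired fit). Interferon and antiviral genes had a median of -0.75 over 17 members, which was -0.46 without control 2 and -0.35 under the stricter filter (camera adjusted p = 0.000286; adjusted p = 0.11 with an estimated correlation). In dhps embryos the list's median was -0.32, called by fry (fry adjusted p = 0.0402) and not by camera (0.0545). Between eif5a1/2 and dhps embryos it was 0.031 (camera adjusted p = 0.699). Against control, the eif5a1/2 call held in 21 of 23 alternatives, with medians of -0.899 to -0.327. The lowest adjusted p of these genes was 0.136, for the nuclease gene isg20 at -0.89 (0.00357 in the paired fit). Of them 8 were lower and 1 higher at an unadjusted p under 0.05, with 0 called by edgeR, 1 lower by DESeq2 and 0 by limma-voom.

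Endocrine pancreas genes had a median of -0.31 over 23 members, -0.21 without control 3 and -0.097 under library totals alone (camera adjusted p = 0.000474; adjusted p = 0.0892 with an estimated correlation). The endocrine factor gene insm1b was at -0.65 (adjusted p = 0.0568, and 0.0206 in the paired fit). Retina and lens genes had a median of -0.22, -0.064 under library totals alone (camera adjusted p = 0.000786; adjusted p = 0.191 with an estimated correlation), with the lens crystallin gene cryba1b at -1.0 (adjusted p = 0.204, and 0.002 in the paired fit). Hox genes had a median of -0.19 over 49 members, -0.045 under library totals alone (camera adjusted p = 0.00106; adjusted p = 0.175 with an estimated correlation), with hoxb13a, expressed in the tail bud, at -0.74 (adjusted p = 0.319). In these 3 lists edgeR called 0 genes in the main fit and 2, 9 and 1 lower in the paired fit, the last hoxa1a (-0.681, adjusted p = 0.0211), limma-voom 0, DESeq2 1, 1 and 0, and 4, 11 and 10 members were lower at an unadjusted p under 0.05.

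The caspase gene casp8 fell by 1.24 ± 0.16 in eif5a1/2 embryos and phlda3, a repressor of Akt signalling, fell by 1.07 ± 0.14. Both had an adjusted p of 0.0296, and they passed the test in 1 and 2 of the 9 fits that leave out 1 library.

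Heat shock genes were higher by a median of 0.16 in eif5a1/2 embryos, 0.33 under library totals alone (camera adjusted p = 0.0172; adjusted p = 0.259 with an estimated correlation). The chaperone genes hsp90aa1.2 and hsp70.3 were at 0.75 and 0.53 (both adjusted p = 0.135, the first 0.0158 in the paired fit). Among its 28 members edgeR called 0, with 4 higher at an unadjusted p under 0.05, 2 higher by DESeq2 and 0 by limma-voom. The call ended without control 2 (adjusted p = 0.208) or eif5a1/2 1 (0.0929), and the median was 0.11 without eif5a1/2 2. The heat shock list was not called in dhps against control, but its median there was similar, at 0.158 (camera adjusted p = 0.0756). In that comparison 9 members were higher and 1 lower at an unadjusted p under 0.05. Between eif5a1/2 and dhps embryos the median was 0.000612 (camera adjusted p = 0.941). Over all 23 alternatives of eif5a1/2 against control the call held in 18, with medians of 0.0811 to 0.327. Liver and gut endoderm genes were also higher (median 0.17, and 0.32 under library totals alone, camera adjusted p = 0.0439; adjusted p = 0.562 with an estimated correlation), with the hepatic factor gene cebpa at 0.40 (adjusted p = 0.222). Of these genes, edgeR and limma-voom called 0, DESeq2 2 higher and 1 lower, and 4 were higher and 1 lower at an unadjusted p under 0.05. The liver and gut call ended without control 2 (median 0.076, adjusted p = 0.551), dhps 2 (0.0598), dhps 3 (0.0556), eif5a1/2 1 (0.051, 0.664) or eif5a1/2 3 (0.0954). Without eif5a1/2 2 the median was 0.27.

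Integrated stress response genes had a median of -0.11, 0.0080 under library totals alone (camera adjusted p = 0.0239; adjusted p = 0.175 with an estimated correlation). The stress factor gene atf4b was at -0.65 (adjusted p = 0.0708, and 0.0158 in the paired fit). The call of the list ended without control 2 (adjusted p = 0.0765) and in the paired fit (median -0.15, adjusted p = 0.0565). Over all 23 alternatives it held in 19. At an unadjusted p under 0.05, 6 members were lower and 1 higher, with 0 called by edgeR or limma-voom and 3 lower and 1 higher by DESeq2. Collagen and matrix genes had a median of -0.14, 0.040 under library totals alone (camera adjusted p = 0.00318; adjusted p = 0.631 with an estimated correlation). The cartilage collagen gene col9a3 was at -0.70 (adjusted p = 0.225, and 0.0222 in the paired fit). Of the collagen and matrix genes 8 were lower and 1 higher at an unadjusted p under 0.05, with 0 called by edgeR or limma-voom and 3 lower by DESeq2. That call ended without control 2 (median -0.024, adjusted p = 0.464), eif5a1/2 1 (0.0929) or eif5a1/2 3 (-0.054, 0.0874), and the median was -0.26 without eif5a1/2 2.

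Among single genes, gnmt (403338), for the glycine N-methyltransferase that consumes S-adenosylmethionine, rose to 19.7 ± 1.1 CPM in eif5a1/2 embryos from 3.68 ± 0.43 in control (log2 2.41 ± 0.16, adjusted p = 0.000284). The membrane protein gene itm2ba (323632) rose to 94.0 ± 2.9 from 27.0 ± 1.6 (1.80 ± 0.11, adjusted p = 0.000209). The heme synthesis gene ppox (664750), for protoporphyrinogen oxidase, fell to 2.42 ± 0.43 CPM from 16.4 ± 1.2 (-2.75 ± 0.17, adjusted p = 0.000209). With eif5a, these 3 genes passed the test in 9 of 9 fits that leave out 1 library. Also higher were pgpep1 (553547, a pyroglutamyl peptidase, 3.29 ± 0.46) and the translation release factor gene etf1b (266989, 1.25 ± 0.15), with adjusted p of 0.0333 and 0.023. The tRNA methyltransferase gene alkbh8 (556362, 1.11 ± 0.17) and the corepressor gene tbl1xr1a (553608, 0.91 ± 0.13) had adjusted p of 0.0457 and 0.0346. Lower were the Wnt agonist gene rspo1 (436625, -1.97 ± 0.24), the lectin gene jac10 (795020, -1.52 ± 0.21) and the mitochondrial ADP/ATP carrier gene slc25a4 (327067, -1.34 ± 0.18), with adjusted p of 0.0228, 0.0296 and 0.0296. The protocadherin gene pcdh1a3 (497126) had 0 reads in each eif5a1/2 library and 34 to 110 reads in the controls, so it was at least 21.1-fold lower (adjusted p = 0.0318, floor of 3 counts per library). It lies in a cluster of similar genes that can share reads. These last 8 genes passed the test in 0 to 4 of the 9 fits that leave out 1 library. With the replicate number as a block over all 9 libraries the calls of etf1b, alkbh8, tbl1xr1a and slc25a4, and that of tubb5, ended (adjusted p = 0.0649, 0.078, 0.0879, 0.078 and 0.0879), and in the paired fit they held.

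The lists that moved with the library axis were called lower in eif5a1/2 embryos too. The median of cytoplasmic ribosomal proteins was -0.35, and -0.21 under library totals alone (camera adjusted p = 1.39e-07; adjusted p = 0.701 with an estimated correlation) and that of nuclear oxidative phosphorylation -0.21, and -0.069 (0.000254; adjusted p = 0.718 with an estimated correlation). Mitochondrial ribosomal proteins had -0.19, and -0.037 under library totals alone (0.000566; adjusted p = 0.718 with an estimated correlation), and translation factors had -0.11, 0.056 under library totals alone, where the call ended at an adjusted p of 0.0554 (0.0439; adjusted p = 0.718 with an estimated correlation). Relative to the control mean, the cytoplasmic ribosomal protein median was -1.07 in eif5a1/2 2 and 0.17 and -0.25 in eif5a1/2 1 and 3. Without eif5a1/2 2 the 4 medians were -0.078, 0.018, 0.014 and 0.027 and the calls ended (adjusted p = 0.77, 0.227, 0.473 and 0.965). Without control 3, oxidative phosphorylation (-0.046, adjusted p = 0.21), mitochondrial ribosomal proteins (-0.067, 0.259) and translation factors (0.00034, 0.259) were not called, and the cytoplasmic ribosomal protein median was -0.15. Without control 2 the 4 medians were -0.60, -0.41, -0.37 and -0.24, and without eif5a1/2 1 they were -0.68, -0.42, -0.44 and -0.25. Without control 1, translation factors were not called (0.199) and the oxidative phosphorylation median was -0.14.

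Of the cytoplasmic ribosomal protein and oxidative phosphorylation genes, 0 were called in eif5a1/2 embryos by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05. Erythrocyte genes had a median of -0.14, 0.0080 under library totals alone (camera adjusted p = 0.00801; adjusted p = 0.631 with an estimated correlation), with ppox the member that fell. The call ended without eif5a1/2 1 (adjusted p = 0.0792) or 2 (0.0727), and the median was -0.26 without control 2 and -0.28 without eif5a1/2 3.

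In eif5a1/2 against control, 26 of 17031 genes changed (0.153%), 11 higher and 15 lower. Under library totals alone 10 were higher and 4 lower. With the replicate number as a block the count was 14 over all 9 libraries, and it was 350 in the paired fit of these 6 libraries, 26 of them among the 26. The paired fit called 9 erythrocyte, 8 skeletal muscle, 5 neuron and 4 collagen genes lower and 3 heat shock genes higher. In it the liver and gut list had 2 higher and 1 lower, the integrated stress response 1 and 2, and interferon genes and translation factors 1 and 1 each. Mitochondrial ribosomal proteins had 1 lower, and cytoplasmic ribosomal proteins and oxidative phosphorylation 0. At an unadjusted p under 0.05 there were 1537, and the groups did not overlap for 12.4% of genes, where chance gives 10%. Without control 1, 2 or 3 the count was 6, 7 or 5, without dhps 1, 2 or 3 it was 5, 7 or 6, and without eif5a1/2 2 or 3 it was 15 or 5. It was 793 with the length slope as a covariate, 215 by DESeq2 and 5 with the 6 libraries fitted alone.

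The direct comparison of eif5a1/2 with dhps morpholino asks where targeting the factor and targeting its modifying enzyme part. The cell death and cell cycle genes casp8 (-2.55 ± 0.17), phlda3 (-2.17 ± 0.14), bbc3 (-2.09 ± 0.14) and cdkn1a (-2.38 ± 0.16) were lower in eif5a1/2 than in dhps embryos, each at an adjusted p of 0.000144. They passed the test in 9 of 9 fits that leave out 1 library.

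Genes of yolk and lipoproteins and of liver and gut endoderm were higher in eif5a1/2 than in dhps embryos. Of 26 yolk and lipoprotein genes, 4 were higher and 24 had positive values (8 higher and 1 lower adjusted over the list alone). Their median was 0.49, and 0.26 under library totals alone, where the median of all genes was -0.19 (camera adjusted p = 6.19e-09; adjusted p = 0.243 with an estimated correlation). Those past the test were the apolipoprotein genes apoa4b.3 (3.39 ± 0.30) and apoa4a (1.61 ± 0.27), rbp4 (1.28 ± 0.24) and the transferrin gene tfa (0.83 ± 0.17), at adjusted p of 0.00052, 0.0209, 0.0347 and 0.0466. Of the 9 fits that leave out 1 library, apoa4a passed in 4, rbp4 in 3 and tfa in 1. Of 28 liver and gut genes, 3 were higher, apoa4a, tfa and the protease inhibitor gene serpina1l (1.16 ± 0.21, adjusted p = 0.0271, in 3 of these fits), with 10 higher and 1 lower adjusted over the list alone. That list's median was 0.41, and 0.19 under library totals alone (camera adjusted p = 2.26e-05; adjusted p = 0.243 with an estimated correlation).

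Among the genes highest in eif5a1/2 relative to dhps embryos, the coagulation factor VII gene f7 (114423) was at 3.61 ± 0.73 CPM in eif5a1/2 against 0.502 ± 0.075 in dhps embryos (2.83 ± 0.31, adjusted p = 0.00197). The cholesterol acyltransferase gene soat2 (564868) was at 7.38 ± 2.2 against 0.960 ± 0.24 (2.92 ± 0.33, adjusted p = 0.00224), and prozb was higher by 2.94 ± 0.29 (adjusted p = 0.000924). With apoa4b.3 they passed the test in 9 of 9 fits that leave out 1 library. The genes ctbs (3.69 ± 0.54, adjusted p = 0.011) and pgpep1 (3.40 ± 0.45, adjusted p = 0.00704) passed in 6, their calls ending without any 1 of the dhps libraries.

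Genes of DNA replication and of mitosis lay higher in eif5a1/2 than in dhps embryos relative to all genes, and their medians were near 0 under library totals alone. Positive values were found for 53 of 61 replication genes (median 0.21, and 0.014 under library totals alone, camera adjusted p = 6.28e-05; adjusted p = 0.243 with an estimated correlation). For mitosis they were found for 37 of 39 genes (median 0.24, and 0.030 under library totals alone, camera adjusted p = 3.01e-05; adjusted p = 0.103 with an estimated correlation). The lowest adjusted p were 0.0963 for the replication clamp loader gene rfc1 (0.37) and 0.119 for the kinetochore gene ndc80 (0.38). In these lists edgeR called 0 and 0 members and limma-voom 0 and 0, with 10 and 6 higher at an unadjusted p under 0.05 and 4 and 2 higher by DESeq2. Neural progenitor genes had a median of 0.19, which was -0.019 under library totals alone (camera adjusted p = 0.00177; adjusted p = 0.319 with an estimated correlation). Higher among them were ascl1b (0.80 ± 0.11), fabp7a (1.11 ± 0.17) and her4.2 (1.14 ± 0.20), at adjusted p of 0.00695, 0.012 and 0.0245, in 6, 5 and 4 of the 9 fits that leave out 1 library. Endoplasmic reticulum chaperone genes had a median of 0.20, and 0.0012 under library totals alone (camera adjusted p = 0.00309; adjusted p = 0.243 with an estimated correlation). In that list herpud1, of protein degradation at the organelle, was higher (0.60 ± 0.13, adjusted p = 0.0483, in 1 of these fits). The difference between the groups in the neuron list was not called by camera (median -0.22, camera adjusted p = 0.072). By fry the list was lower in eif5a1/2 embryos (fry adjusted p = 0.0111), although edgeR called 2 of its members higher and 0 lower.

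The genes lowest in eif5a1/2 relative to dhps embryos included rspo1, at 1.64 ± 0.33 against 18.6 ± 4.1 CPM (-3.52 ± 0.24, adjusted p = 0.000144), and rnf213b, at 0.224 ± 0.092 against 3.75 ± 0.28 (-3.96 ± 0.32, adjusted p = 0.000319). The others were cdkn2a/b (-3.87 ± 0.67, adjusted p = 0.0249), the leukotriene receptor gene ltb4r (100329657, -3.08 ± 0.59, adjusted p = 0.0372) and the pocket protein gene rbl2 (100331892, -2.86 ± 0.58, adjusted p = 0.0466). For pcdh1a3, 0 reads stood against 19 to 57 per dhps library, at least 9.32-fold lower (adjusted p = 0.0193). The calls of rspo1 and rnf213b held in 9 of 9 fits that leave out 1 library, those of pcdh1a3, cdkn2a/b, ltb4r and rbl2 in 6, 5, 3 and 2.

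Collagen and matrix genes had a median of -0.38 in eif5a1/2 against dhps, -0.18 without dhps 1 (camera adjusted p = 7.83e-05; adjusted p = 0.605 with an estimated correlation). The member past the test, the basement membrane collagen gene col15a1b, was higher (1.06 ± 0.19, adjusted p = 0.0271, in 4 of the 9 fits that leave out 1 library), and 5 were lower and 1 higher adjusted over the list alone. Ribosome biogenesis genes had a median of -0.12, and -0.32 under library totals alone (camera adjusted p = 0.00216; adjusted p = 0.783 with an estimated correlation), with nolc1 lower (-1.25 ± 0.12, adjusted p = 0.000778). The call ended without dhps 3 (-0.064, 0.0634) or eif5a1/2 2 (-0.076, 0.268), and the median was -0.18 without dhps 1 and -0.20 without eif5a1/2 1. Skeletal muscle genes had a median of -0.13, and -0.34 under library totals alone (camera adjusted p = 0.00869; adjusted p = 0.605 with an estimated correlation), although the member past the test, eno3, was higher (1.69 ± 0.29, adjusted p = 0.0258, in 3 of these fits). That call ended without dhps 3 (-0.075, adjusted p = 0.127) or eif5a1/2 2 (-0.037, 0.477), and the median was -0.27 without eif5a1/2 1.

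Pronephros genes had a median of -0.29 (camera adjusted p = 0.0216; adjusted p = 0.444 with an estimated correlation), with the kidney factor gene pax8 at -0.73 (adjusted p = 0.121). The call ended under library totals alone (adjusted p = 0.0759) and without dhps 1 (-0.18, 0.0741), eif5a1/2 1 (-0.16, 0.091) or eif5a1/2 3 (0.0743). Notochord and floor plate genes had a median of -0.17, and -0.33 under library totals alone (camera adjusted p = 0.0463; adjusted p = 0.319 with an estimated correlation), with the matrix signalling gene cyr61 at -0.45 (adjusted p = 0.151). The call ended without control 1 (0.0558), dhps 1 (0.0558), dhps 3 (0.127), eif5a1/2 2 (0.0749) or eif5a1/2 3 (-0.078, 0.164). In the pronephros and notochord lists edgeR and limma-voom called 0 members, DESeq2 2 lower and 0, and 6 lower and 1 higher, and 4 lower, had an unadjusted p under 0.05.

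Cytoplasmic ribosomal proteins were called higher in eif5a1/2 than in dhps embryos (median 0.49, and 0.20 under library totals alone, camera adjusted p = 1.96e-07; adjusted p = 0.783 with an estimated correlation) and moved with the library axis. So did nuclear oxidative phosphorylation (0.31, and 0.063 under library totals alone, 2.58e-05; adjusted p = 0.84 with an estimated correlation) and mitochondrial ribosomal proteins (0.22, and -0.042 under library totals alone, where the call ended at an adjusted p of 0.433; 0.0427, adjusted p = 0.923 with an estimated correlation). The member of these lists past the test was rpl22l1, which was higher (1.69 ± 0.25, adjusted p = 0.0109, in 6 of the 9 fits that leave out 1 library). Over the 5 libraries with a positive length slope, where the eif5a1/2 group is eif5a1/2 2 alone, their medians were -0.33, -0.35 and -0.37. Without eif5a1/2 1 they were 0.18, 0.10 and -0.012 and the calls ended (adjusted p = 0.0623, 0.335 and 0.593), and without eif5a1/2 2 they were 0.77, 0.55 and 0.42. The last call also ended without dhps 1 (0.373) or eif5a1/2 3 (0.203).

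Between eif5a1/2 and dhps embryos 302 of 17031 genes differed (1.77%), 159 higher and 143 lower in eif5a1/2 embryos. Under library totals alone 57 were higher and 76 lower. At an unadjusted p under 0.05 there were 2476, and the groups did not overlap for 20.9% of genes, where chance gives 10%. The count was 850 without eif5a1/2 2 and 148 and 75 without eif5a1/2 1 and 3. It was 70, 96 and 66 without dhps 1, 2 and 3, and 141 and 184 without control 1 and 3. It was 827 by DESeq2 and 1590 with the length slope as a covariate.

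**Figure D3:**
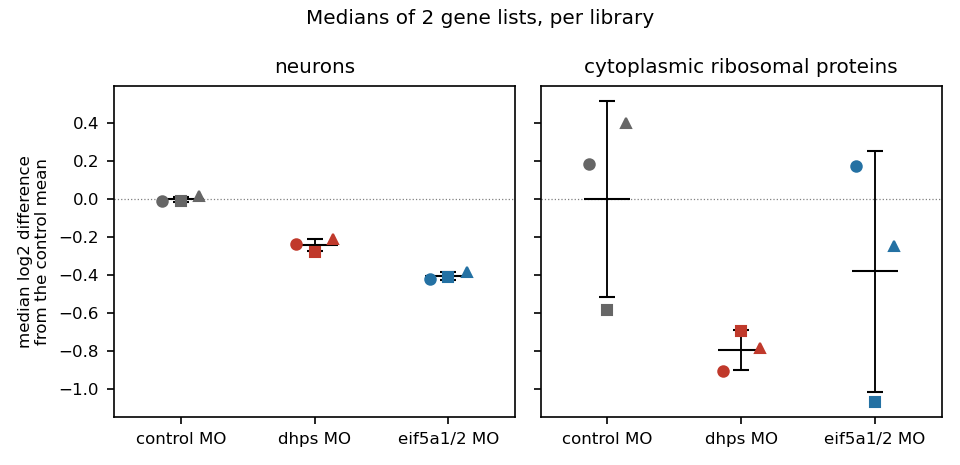
Median log2 CPM of a list's members relative to the control mean in each of the 9 libraries (points), by injected morpholino, for lists named in the panel titles. The neuron list lies at -0.21 or below in all 6 knockdown libraries (under library totals alone its dhps median against control is 0.12, and -0.25 relative to all genes), and the cytoplasmic ribosomal protein list at -0.58 in control 2 and -1.07 in eif5a1/2 2.

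The 2 knockdowns were then set side by side against the shared controls. In both, itm2ba (0.56, adjusted p = 0.0495, in dhps and 1.80 in eif5a1/2) and si:ch211-210c8.6 (0.65 and 1.61) rose and slc25a4 (-1.18, adjusted p = 0.0143, and -1.34) fell. In opposite directions moved rspo1 (1.55 and -1.97), casp8 (1.31 and -1.24), phlda3 (1.1 and -1.07) and si:dkey-204l11.1 (1.55 and -1.55), each higher in dhps and lower in eif5a1/2 embryos. The symbols with a clone name were named after their values were seen. With the paired fit for eif5a1/2 against control, 9 genes were higher and 19 lower in both, 10 were higher in dhps and lower in eif5a1/2 and 1 the other way. Independent sets of these calls would give 0.942, 1.36, 1.07 and 1.2, which leaves out the shared controls. Simulated unchanged groups that keep the pairing and share the controls gave 0 calls in either comparison in 10 simulations, so they set no level either. Among them cdkn1a was lower in eif5a1/2 (-0.822, adjusted p = 0.0226) and higher in dhps embryos, and mibp2 (-0.761, 0.017) was lower in both.

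In the main fit the overlap was set beside chance. Independent sets of calls would there give 0.0672 genes higher in both, where 2 were found, and 0.102 lower in both, where 1 was found. They would give 0.0916 higher in dhps and lower in eif5a1/2, where 4 were found, and 0.0749 the other way, where 0 were found by edgeR. Simulated unchanged groups, with controls simulated as well, gave 0 calls in either comparison in 10 simulations, so their 0 shared calls set no level for the overlap.

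Among the lists, 9 were called in both comparisons with control. Neurons, retina and lens, erythrocytes, cytoplasmic and mitochondrial ribosomal proteins, nuclear oxidative phosphorylation and translation factors were called lower in both, of which, under library totals alone, the medians of neurons and mitochondrial ribosomal proteins turned positive in dhps and those of erythrocytes and translation factors in both. That scaling moves all genes (median 0.365 and 0.176), and relative to all genes these medians stayed negative, at -0.25 and -0.341 in dhps and at -0.339, -0.254, -0.168 and -0.12 for erythrocytes and translation factors in dhps and then eif5a1/2. With an estimated correlation the neuron list kept its calls and the other 6 lost theirs in both comparisons (adjusted p = 0.191 to 0.718). Liver and gut endoderm was called lower in dhps and higher in eif5a1/2 embryos, and under library totals alone its dhps median turned positive (-0.143 relative to all genes). With an estimated correlation neither of its calls held (adjusted p = 0.54 and 0.562). Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of 0.637 and a Spearman rho of 0.601. On mean log2 CPM the r was 0.627 and the covariance 0.15, against 0.511 and 0.0635 for simulated unchanged groups, a difference in covariance of 0.0863. The same sign was found for 72% of genes against 66.9%. In these simulations the controls were simulated too, each gene drawn independently from its mean over all libraries, without the library axis or the pairing. The simulated levels may thus be too low, and the difference cannot be read as beyond what shared controls give. No split of 3 controls leaves 2 on each side, so none was made and part of the excess may come from the shared controls, and r was 0.0247 without eif5a1/2 2 and 0.885 without control 2.

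**Figure D4:**
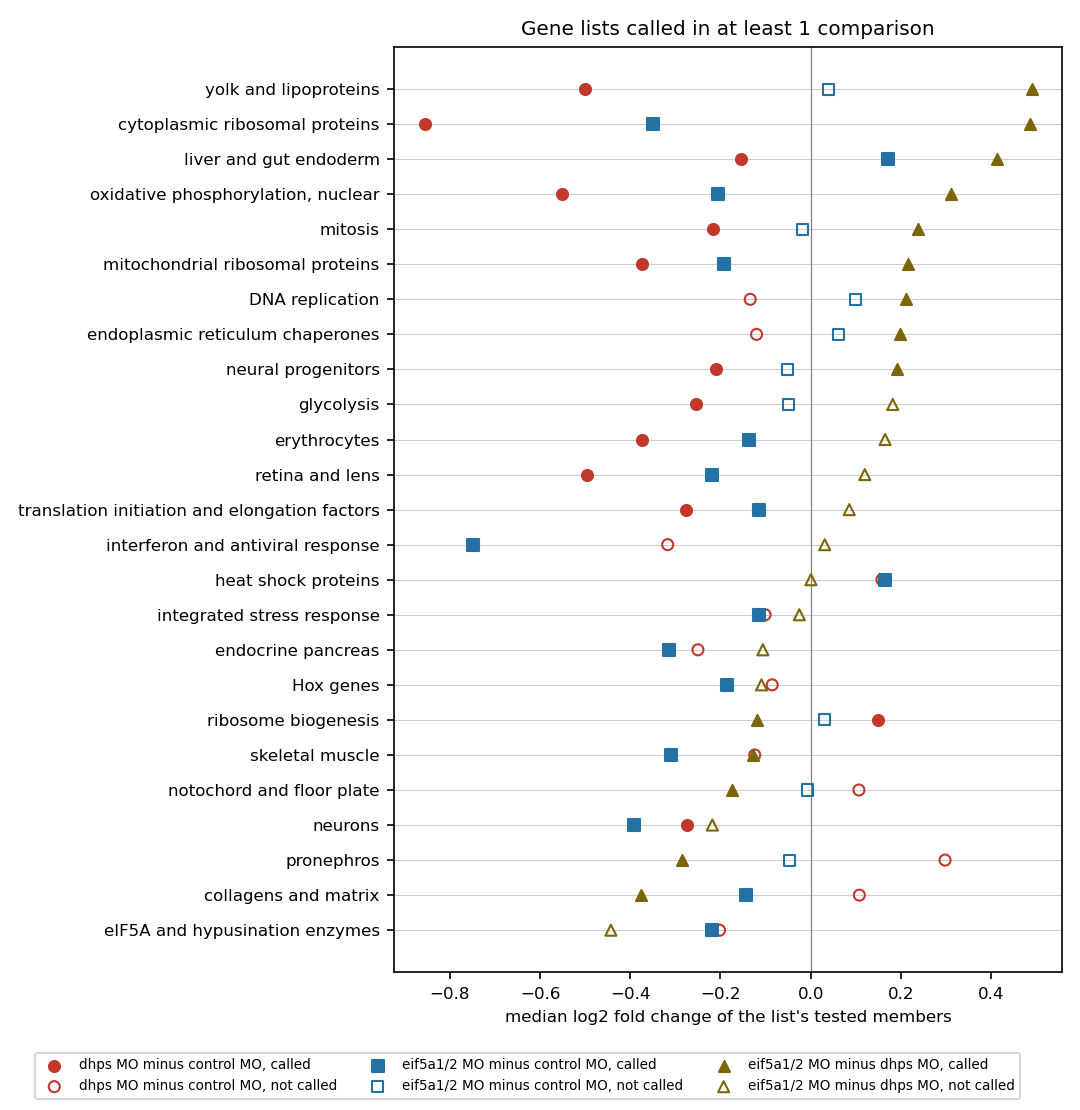
Median log2 fold change of the tested members of gene lists called in at least 1 comparison, for dhps minus control, eif5a1/2 minus control and eif5a1/2 minus dhps morpholino; filled marks are lists called by camera and open marks lists not called. The neuron list lies at -0.28 in dhps and -0.39 in eif5a1/2 embryos against control, and under library totals alone the medians of mitosis, mitochondrial ribosomal proteins, translation factors, liver and gut, erythrocytes, neurons, neural progenitors and glycolysis turn positive in dhps against control, those of integrated stress response, translation factors, collagens and erythrocytes in eif5a1/2 against control, and those of mitochondrial ribosomal proteins and neural progenitors turn negative in eif5a1/2 against dhps, while relative to all genes each of them keeps its direction.

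With the length slope as a covariate the calls of liver and gut (median -0.055, adjusted p = 0.0737) and translation factors (-0.0016, 0.766) ended in dhps against control. The medians of retina and lens and of erythrocytes were -0.30 and -0.22 there. In eif5a1/2 against control translation factors were not called (-0.020, adjusted p = 0.117), the collagen median was -0.24, and those of mitochondrial ribosomal proteins and oxidative phosphorylation were -0.095 and -0.11. Over all 23 alternatives there, the calls of these last 2 lists held in 17 each. In eif5a1/2 against dhps the calls of cytoplasmic ribosomal proteins (0.0042, adjusted p = 0.795), pronephros (-0.10, 0.182) and notochord and floor plate (-0.16, 0.0539) ended. The medians of yolk and lipoproteins, collagens, ribosome biogenesis and skeletal muscle were 0.31, -0.20, -0.25 and -0.27. Over the 5 libraries with a positive length slope, with a lone control 2 and a lone eif5a1/2 2, the calls of erythrocytes (adjusted p = 0.151), liver and gut (0.147), mitochondrial ribosomal proteins (0.344), translation factors (0.694) and oxidative phosphorylation (0.0695) ended in dhps against control. Those of collagens (0.153), liver and gut (0.767) and erythrocytes (0.231) ended in eif5a1/2 against control. Between eif5a1/2 and dhps the calls of endoplasmic reticulum chaperones (0.127, adjusted p = 0.158), liver and gut (0.234, 0.0633), collagens (-0.0924, 0.369), pronephros (-0.0801, 0.757) and notochord (-0.11, 0.369) ended. With members of 1 list only, the calls of liver and gut, translation factors and glycolysis in dhps (adjusted p = 0.0507, 0.0507 and 0.051) and of pronephros and notochord in the direct comparison (0.128 and 0.227) ended.

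Of the 38 lists tested, 14 were called in dhps against control (2 higher, 12 lower), 17 in eif5a1/2 against control (2 higher, 15 lower) and 15 in eif5a1/2 against dhps (9 higher, 6 lower). With an estimated correlation, the calls that held were those of the neuron list in the 2 comparisons with control. In the direct comparison 0 held. By fry 10, 8 and 8 lists were called in the 3 comparisons, of which 7, 6 and 6 were among the calls of camera. Not called by fry in dhps against control were cytoplasmic and mitochondrial ribosomal proteins (fry adjusted p = 0.166 and 0.356), oxidative phosphorylation (0.216), translation factors (0.382), ribosome biogenesis (0.204), liver and gut (0.112) and erythrocytes (0.166). For eif5a1/2 against control they were the same lists without ribosome biogenesis (0.627, 0.687, 0.687, 0.645, 0.438 and 0.389), and collagens (0.517), heat shock (0.0848), skeletal muscle (0.0562), retina and lens (0.0562) and Hox genes (0.0568). In the direct comparison they were cytoplasmic and mitochondrial ribosomal proteins (0.557 and 0.811), oxidative phosphorylation (0.637), ribosome biogenesis (0.415), collagens (0.236), skeletal muscle (0.407), neural progenitors (0.0684), pronephros (0.192) and notochord (0.0653). Not called by camera in any of the 3 comparisons were 12 lists, given here with their lowest adjusted p. They were endothelium (0.0668), exocrine pancreas (0.0813), myeloid cells (0.111), pigment cells (0.185), posterior mesoderm progenitors and segmentation (0.193) and epidermis and ionocytes (0.243). The others were hatching gland (0.26), autophagy and lysosome (0.665), polyamine metabolism (0.681), neural crest (0.705), cholesterol synthesis (0.781) and heart (0.802).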

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

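The tests of the ribosomal protein and neuron lists in this part were chosen after the results were seen, and the splits of the samples were chosen earlier. Dixon's test for a single deviating sample was not run, because groups of 3 libraries are below its limit here.

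Genes called in opposite directions in the 2 knockdowns against control were picked out. Their difference in eif5a1/2 against dhps embryos follows from that choice, so it is given without a test. The difference was -2.55 for casp8 and -2.17 for phlda3, genes of apoptosis and Akt signalling, and -3.52 for the Wnt agonist gene rspo1. It was -3.11 for si:dkey-204l11.1. The list of liver and gut endoderm differed by a median of 0.414. Against control, the eif5a1/2 calls of casp8, phlda3 and rspo1 held in 1, 2 and 4 of 9 fits that leave out 1 library. The eif5a1/2 call of liver and gut held in 4 of these fits. Under library totals alone, which moved the median of all genes by 0.365, the dhps median of this list was 0.222, or -0.143 relative to all genes (adjusted p = 0.0103).

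Genes for cytoplasmic ribosomal proteins lay lower in dhps embryos. The length difference between libraries may account for the larger part, since 24.7% of the median was left with the length slope as a covariate. Whether it accounts for the whole cannot be told apart: the remaining median of -0.212 was called with the preset correlation and had an adjusted p of 0.544 with an estimated one. Over the alternatives the adjusted p of this list ran from 4.4e-52 to 0.54. An effect of the knockdown on these genes stays open.

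Genes of neurons lay lower in both knockdowns, in 6 of 6 knockdown libraries, and under library totals alone the dhps median turned positive but lay at -0.25 relative to all genes (adjusted p = 0.000945). The length difference is argued against as the cause, since at least 102% of the median was left in each comparison with the length slope as a covariate and the list stayed called, and so is a single high control library, the lowest control lying 0.198 (log2) above the highest knockdown library. A delay of development stays open, because the list of posterior mesoderm and segmentation, genes of younger stages, was called by camera in neither comparison and the higher of its medians was -0.0465. By fry, which does not compare with other genes, it was lower in eif5a1/2 (adjusted p = 0.00792) and not called in dhps embryos (0.166). Fewer neurons and lower transcript levels per neuron cannot be separated in RNA of whole embryos, and neither was tested.

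The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In dhps against control, 1 of 10 splits gave 220 genes, the real one, and the highest other gave 1. For eif5a1/2 against control, 2 of 10 gave at least 26 genes, and the highest other gave 3615. That split sets control 1, control 3 and eif5a1/2 1 against control 2, eif5a1/2 2 and eif5a1/2 3, which follows the order of the libraries on the first principal component and points to a structure of the samples. It keeps control 1 with eif5a1/2 1, while the real split parts all 3 same-numbered pairs. The 3 other splits that part them gave 0 genes by edgeR in the main fit, against 26 (183, 221 and 332 at an unadjusted p under 0.05, against 1537), and 0 in the paired fit, against 350. With 4 such splits no share under 0.05 can be had. For eif5a1/2 against dhps, 1 of 10 gave 302 genes, and the highest other gave 0. For the lists, 1 of 10 splits reached the real count in each comparison, with 14 against 11, 17 against 13 and 15 against 11 for the highest other.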

How the results depend on the processing

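The fits with the length slope as a covariate, the length trend removed, 1 surrogate variable, the libraries of positive or negative length slope alone and the paired fit were chosen after the data were seen. Where a result changed, the cause was not tested unless the setting itself shows it.

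The number of genes changed depended on the setting in each comparison. In dhps against control (220 genes) it was 97 under library totals alone, 951 with the length slope as a covariate, 331 with the length trend removed, 1007 with 1 surrogate variable and 898 by DESeq2. By construction it was lower with a 2-fold minimum (123) and at an adjusted p under 0.01 (64). Leaving out 1 library gave 44 to 807.

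For the 26 genes of eif5a1/2 against control it was 14 under library totals alone, 14 with a replicate block over all 9 libraries, 350 in the paired fit with the block over these 6, 793 with the covariate, 827 with 1 surrogate variable and 215 by DESeq2. It was 74 over the libraries with a positive length slope, where 1 library of each group is left and the spread comes from dhps, and 125 over those with a negative one, 5 with the 2 groups alone and 5 at an adjusted p under 0.01. Leaving out 1 library gave 5 to 19 (without eif5a1/2 1).

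For the 302 genes of eif5a1/2 against dhps it was 133 under library totals alone, 183 with a replicate block, 1590 with the covariate, 1894 with 1 surrogate variable and 827 by DESeq2. It was 595 over the libraries with a positive length slope, with eif5a1/2 2 as the lone eif5a1/2 library, 156 with the 2 groups alone, 155 with a 2-fold minimum and 75 at an adjusted p under 0.01. Leaving out 1 library gave 66 to 850. The genes called with the covariate included 219 of 220, 26 of 26 and 302 of 302. Over the 3 groups a library correlated best with its own number in 5 of 18 combinations, 4 of them between control and eif5a1/2. The block over 9 libraries thus also ties dhps libraries that show no pairing. Of the lists in eif5a1/2 against control, the paired fit ended the call of the integrated stress response, and the block over 9 libraries ended none.

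Genes changed in the same direction in both knockdowns numbered 3, or 0 by edgeR with a replicate block, 144 with the covariate and 152 with 1 surrogate variable, and 0 to 3 with 1 library left out. There the Pearson r across genes ran from 0.0247 to 0.885.

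The lists called in the 3 comparisons numbered 14, 17 and 15, or 1, 1 and 0 with an estimated correlation and 10, 8 and 8 by fry. Leaving out 1 library gave 14 to 19, 12 to 20 and 12 to 16 lists.

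Some lists changed direction. In dhps against control the median of mitochondrial ribosomal proteins was 0.0493 with the covariate, 0.099 with 1 surrogate variable and 0.0409 over the libraries with a positive length slope. For translation factors camera turned upward in the same 3 settings, with medians of -0.00161, 0.0294 and 0.0392. In eif5a1/2 against control, with 1 library left out, mitochondrial ribosomal proteins ran from -0.435 to 0.0139 and nuclear oxidative phosphorylation from -0.424 to 0.0181, both turning without eif5a1/2 2.

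Between eif5a1/2 and dhps embryos, mitochondrial ribosomal proteins ran from -0.0119 (without eif5a1/2 1) to 0.425. They stood at -0.13 with the covariate, -0.0996 with 1 surrogate variable, 0.0252 with the length trend removed, where camera turned downward, and -0.369 over the libraries with a positive length slope. Nuclear oxidative phosphorylation was at -0.0553, -0.00934 and -0.346 with the covariate, 1 surrogate variable and the positive length slope, and cytoplasmic ribosomal proteins at -0.332 in the last. The dohh transcript in dhps embryos was at 0.375 with 1 surrogate variable (adjusted p = 0.0279).

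The neuron list was called in each of 21 alternatives in dhps and 23 in eif5a1/2 against control. Of 32, 15 and 30 named genes called in the 3 comparisons, 31, 15 and 30 were kept with the covariate, 29, 15 and 30 by DESeq2 and 17, 8 and 21 under library totals alone. With the 2 groups alone 31, 4 and 24 were kept and with the replicate block over 9 libraries 20, 10 and 25, while the paired fit kept 15 of the 15 in eif5a1/2 against control.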

Other observations

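The genes, single members of lists and neighbour counts in this part were chosen after their values were seen.

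The methionine adenosyltransferase gene mat2al, whose product makes S-adenosylmethionine, rose by 1.62 ± 0.13 in dhps embryos (adjusted p = 0.00126) and was lower by -2.05 ± 0.13 in eif5a1/2 than in dhps embryos (adjusted p = 0.000144). Between eif5a1/2 and control embryos it was at -0.43 (adjusted p = 0.353). The gene gnmt, whose product consumes the same metabolite, was higher in eif5a1/2 than in dhps embryos (2.71, adjusted p = 0.000144), with 2.4 to 3.35 CPM in dhps and 3.18 to 3.98 in control libraries. The endothelial matrix gene mmrn2b rose by 1.98 in dhps embryos (adjusted p = 0.000554), the activin antagonist gene fsta by 1.75 (adjusted p = 0.00138) and the growth factor binding gene igfbp7 by 1.1 (adjusted p = 0.00172). In eif5a1/2 against dhps embryos they were at -1.90, -1.87 and -1.47 (adjusted p = 0.000161, 0.000254 and 0.000161).

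Single members changed in lists that were not called in dhps embryos. Lower were the melanin synthesis gene tyrp1b (-1.11, adjusted p = 0.0125), the pharyngeal arch factor gene barx1 (-1.21, 0.0331) and the cholesterol synthesis gene mvda (-1.72, 0.00713). The lysozyme gene lyz of myeloid cells (-1.24, 0.0388) and the stress gene nupr1 (-1.4, 0.0413) were lower as well. The hatching enzyme gene he2 rose (1.1, 0.042). In eif5a1/2 against dhps embryos, members of the integrated stress response, slc3a2b (-0.80, adjusted p = 0.0165) and atf3 (-0.91, 0.0441), and the antiviral nuclease gene isg20 (-1.25, 0.0107) were lower.

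Changed genes were also counted by place, as pairs within 5 tested genes of each other among 16460 tested genes with a known order. In dhps against control there were 23 pairs, where 1000 random sets gave a mean of 14.3 and 24 of them as many. For eif5a1/2 against control there were 2, where the mean was 0.196 and 13 sets gave as many, and in eif5a1/2 against dhps 35, where the mean was 27.2 and 85 sets gave as many.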
